A study of Drosophila melanogaster with 8 samples.

How the data were processed

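RNA abundance in fly heads was measured with Affymetrix Drosophila Genome 2.0 arrays, on which biotin-labelled RNA is hybridized and each transcript is read by a probe set, a group of short probes summarized to 1 value. The deposited values are log2 intensities, and the submitters' processing notes name GCRMA, a method that corrects the background of each probe and normalizes the arrays together. Its version and settings are not stated. The lowest value was 2.32 on each of the 8 arrays, and a value close to it means that a transcript was not seen above background. Such values are not quantitative, so a fold against them is not quantitative either. The number of arrays limits the precision of every value given here.

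The 8 arrays cover 4 strains, each collected 4 h (ZT4) and 16 h (ZT16) after lights on following 3 days of 12 h light and 12 h dark. The w1118 strain is the control of a strain in which a part of the miRNA cluster is deleted, called the knockout here. A strain with the tim-gal4 driver is the control of a strain in which tim-gal4 drives a transgene of the cluster, called overexpression here. The genotype labels give a yw background to both of these strains, and the titles of the tim-gal4 control name it yw. Each combination of strain and time has 1 array, so there are no replicates. Differences between 2 single arrays are given as values with no test.

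The table holds 18952 probe sets. The 183 control probe sets were left out of the comparisons. Of the other 18769, 13647 carried 1 gene symbol in the platform annotation, 402 carried several and 4720 carried none. Probe sets with a log2 value of at least 4 on at least 2 of the 8 arrays were kept, which left 8300. Of these, 7347 carried 1 symbol and stood for 6861 genes. A RefSeq gene table (Drosophila genome Release 6) gave the order of genes along the chromosomes.

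Fits were made with limma 3.58.1 in R 4.3.3, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for the tables and figures. The model held strain as a block and time of collection, which leaves 3 residual degrees of freedom. Its error is the part of the time change that differs between strains, since no other error can be had from 1 array per condition. A transcript whose time change truly differs between strains therefore has a large error in this model. From it came ZT16 against ZT4 over the 4 strains, the knockout against w1118, overexpression against the tim-gal4 control, and the w1118 control against the tim-gal4 control as a measure of how far 2 control strains differ. A further fit for each manipulated strain, with 2 residual degrees of freedom, tested whether its time change differed from that of the other strains. The p-values are two-sided, from limma's moderated test, with Benjamini-Hochberg adjustment over the 8300 probe sets within each of the 6 comparisons. The threshold was an adjusted p under 0.05. A probe set past it is called higher or lower here, or said to have risen or fallen. All errors given with log2 differences are standard errors (SE) from these fits. A seventh question, whether the knockout and overexpression move transcripts in opposite directions, was described by counts of probe sets that differ at least 2-fold the same way at both times in each comparison, set against the overlap that unrelated lists would give.

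Apart from those described as picked later, the genes named in the text were chosen by a rule fixed before the data were examined. So were the model, the filter, the gene lists and the alternatives of the closing section except those described there as chosen later. Named first are the genotype markers and the gene annotated over the cluster. For the time of day come all core clock genes measured. Then come the 12 largest rises and 12 largest falls among called probe sets with 1 symbol and the same direction in every pair of arrays, and the 2 to 4 members of each gene list with the largest called difference, or with the largest difference where none was called. The control strains have 5 in each direction. Where a gene has several probe sets, the one with the highest mean stands for it.

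The 20 lists hold the core clock, head transcripts known to cycle, feeding and metabolic hormones, carbohydrate metabolism, lipid metabolism, antimicrobial and humoral immune genes, stress and heat shock genes, detoxification enzymes, phototransduction and photoreceptors, chemoreception and odorant binding, ribosomal proteins, sex-biased fat body genes, neurons, glia, muscle, gut enzymes, testis, accessory gland, ovary and eggshell, and hemocytes. The gut, testis, accessory gland and ovary lists stand for tissue that dissected heads should not hold. For each list the called members were counted, also with p-values adjusted over the list alone. A shift of the list against all other genes was tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 19 lists that had at least 3 members above the filter, and again with a correlation estimated from the residuals.

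The procedure was tested on simulated data with the same number of arrays, in which 200 of 8300 probe sets changed. Its noise was drawn independently for each probe set. The rates below may therefore not hold where many probe sets shift together on single arrays. A difference of 1 on the log2 scale was recovered in 89% of cases for the time of day, 61.8% for the knockout and 61.6% for overexpression. The share of false calls was 4.84%, 4.53% and 4.45% there. For a time change in 1 strain, a difference of 1 was recovered in 0.2% (knockout) and 0.3% (overexpression) of cases and a difference of 2 in 57.4% and 60.8%. The share of false calls was 9.25% and 8.55% in these 2 fits, above the 5% set by the threshold.

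The alternatives tried were other filters and floors on low values, quantile normalization or median centring on top of the deposited values, trended and robust variance moderation, 1 value per gene, a 2-fold threshold, fits without each array or strain in turn, fits of the 4 arrays of 1 comparison alone, and other treatments of the strain block. After the data had been seen, fits without the knockout ZT16 and tim-gal4 control ZT16 arrays, fits with a term for them, and fits without the 372 probe sets that were at least 2-fold higher in both of those arrays than in each of the other 6 were added. The gene white, a genotype marker, was not analysed here.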

Results

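The data describe RNA from the heads of flies of 4 strains, each sampled in the light phase (ZT4) and in the dark phase (ZT16), with 1 array for each of the 8 conditions and no replicates. By the title of the study, the miRNA cluster miR-959 to miR-964 oscillates and acts on feeding time and other outputs of the circadian clock. Each array had between 39.7% and 40.7% of its probe sets at a log2 value of at least 4, and its highest value lay between 14.8 and 14.9.

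The genotype markers were read first. The gene tim, which carries the promoter used in the driver, had log2 values of 6.0 at ZT4 and 11.17 at ZT16 in the w1118 control, 5.82 and 10.82 in the knockout, 7.66 and 10.55 in the tim-gal4 control, and 6.99 and 10.77 under overexpression. A second tim probe set read 2.36 and 3.83 in the w1118 control and 2.33 and 3.22 in the knockout, against 4.75 and 8.06 in the tim-gal4 control and 4.64 and 8.49 under overexpression. The pigment gene y read 4.20 and 2.58 in the w1118 control, 3.39 and 2.35 in the knockout, and between 2.33 and 2.35 on the 4 arrays of the yw strains. DIP-theta, the gene annotated over the miRNA cluster, read 5.98 and 6.02 in the w1118 control, 5.57 and 5.17 in the knockout, 5.28 and 5.10 in the tim-gal4 control, and 5.01 and 5.08 under overexpression. It was called neither in the knockout comparison (log2 difference -0.63, SE 0.15, adjusted p = 0.182 in limma) nor in the overexpression comparison (-0.14, SE 0.15, adjusted p = 0.533 in limma). Where its probes lie relative to the deletion was not analysed here.

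Markers of tissues outside the head were at background on 6 arrays and high on 2, the knockout ZT16 array and the tim-gal4 control ZT16 array, called the 2 arrays with body-tissue markers here. Acp98AB, a seminal fluid protein of the male accessory gland, read 12.15 and 11.64 there, 4.29 on the knockout ZT4 array and at most 2.37 on the other 5 arrays. The digestive protease alphaTry read 9.83 and 11.18 there against 2.32 elsewhere, and the testis gene ocn 8.51 and 8.33 against at most 2.33. Each of these genes was picked after the data were seen, as the member of its list with the highest mean on the 2 arrays. The median of the 13 accessory gland genes rose from ZT4 to ZT16 by 7.08 on the log2 scale in the knockout and by 6.17 in the tim-gal4 control, and its change was 0 in both other strains. For the 8 gut enzymes these medians were 7.15 and 6.59 against 0, and for the 13 testis genes 4.20 and 4.27 against 0.01 and 0. The lists hold only members that passed the filter, which a gene at background on 6 arrays can pass only through the other 2. Over all 26 gut enzymes on the array, the median level was 3.83 at ZT16 in the knockout and 3.46 in the tim-gal4 control. The 12 muscle genes had median changes of 0.61 and 0.78 on the log2 scale in these strains, the 15 neuronal genes -0.29 and -0.24. None of the 19 ovary and eggshell genes on the array passed the filter. In all, 372 probe sets (4.48% of those kept) were at least 2-fold higher in both arrays than in each of the other 6.

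**Figure D1:**
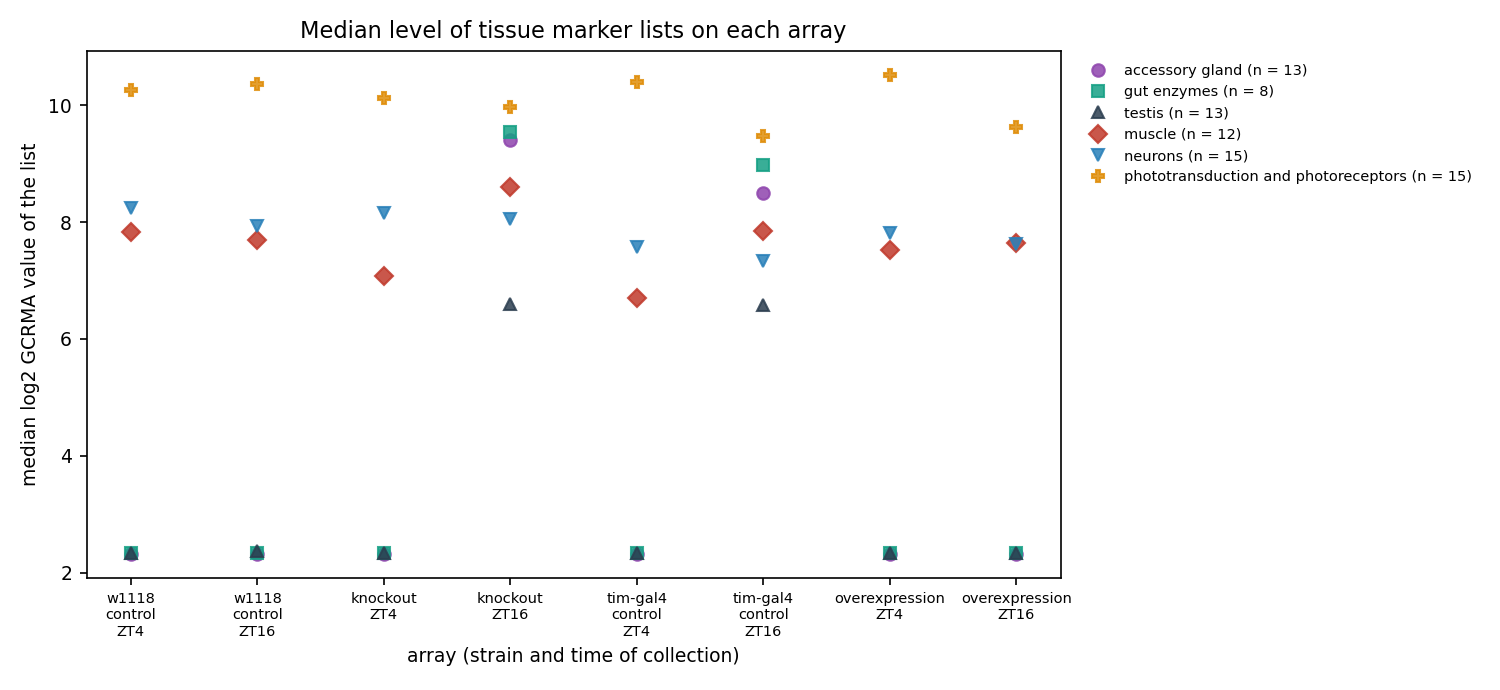
Each point is the median log2 GCRMA value, on 1 array, of the members of a tissue marker list that passed the filter. The 8 arrays lie along the horizontal axis. The accessory gland, gut and testis lists lie near the lowest value of 2.32 on 6 arrays and between 6.59 and 9.53 on the knockout ZT16 and tim-gal4 control ZT16 arrays.

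The first comparison asked which transcripts differ between ZT16 and ZT4 over the 4 strains. Genes at the core of the circadian clock were among the largest changes called. The repressor genes tim, vri and per rose at ZT16 by 4.21 (SE 0.41), 3.40 (SE 0.31) and 3.38 (SE 0.15) on the log2 scale, that is 18.5-fold, 10.5-fold and 10.4-fold, over 4 pairs of arrays. Clk, which encodes an activator of these genes, fell by 2.29 (SE 0.19) and cry, the blue-light receptor of clock cells, fell by 2.28 (SE 0.12) on the log2 scale. Adjusted p-values in limma were 0.0157 for per, 0.0200 for cry and 0.0499 for the other 3. The directions were the same in all 4 strains, with changes of per of 3.70 in the w1118 control, 3.49 in the knockout, 2.88 in the tim-gal4 control and 3.45 under overexpression.

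Of the 13 core clock genes measured, 3 rose, 2 fell and 8 were not called, and 7 passed when adjusted over the list alone. Pdp1, an activator of Clk, differed by 1.18 (SE 0.16, adjusted p = 0.0651 in limma), and the transcriptional repressor cwo by 0.66 (SE 0.20, adjusted p = 0.228 in limma). The differences of Fbxl4, dco, slmb, cyc, Pdf and Pdfr lay between -0.13 and 0.28. Among 13 head transcripts known to cycle, Slob, which encodes a protein that binds the Slowpoke potassium channel, rose by 2.21 (SE 0.22) on the log2 scale, although another probe set of the gene had the opposite sign. CG42329 fell by 3.04 (SE 0.25), and 11 members were not called, while 9 passed when adjusted over the list alone.

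**Figure D2:**
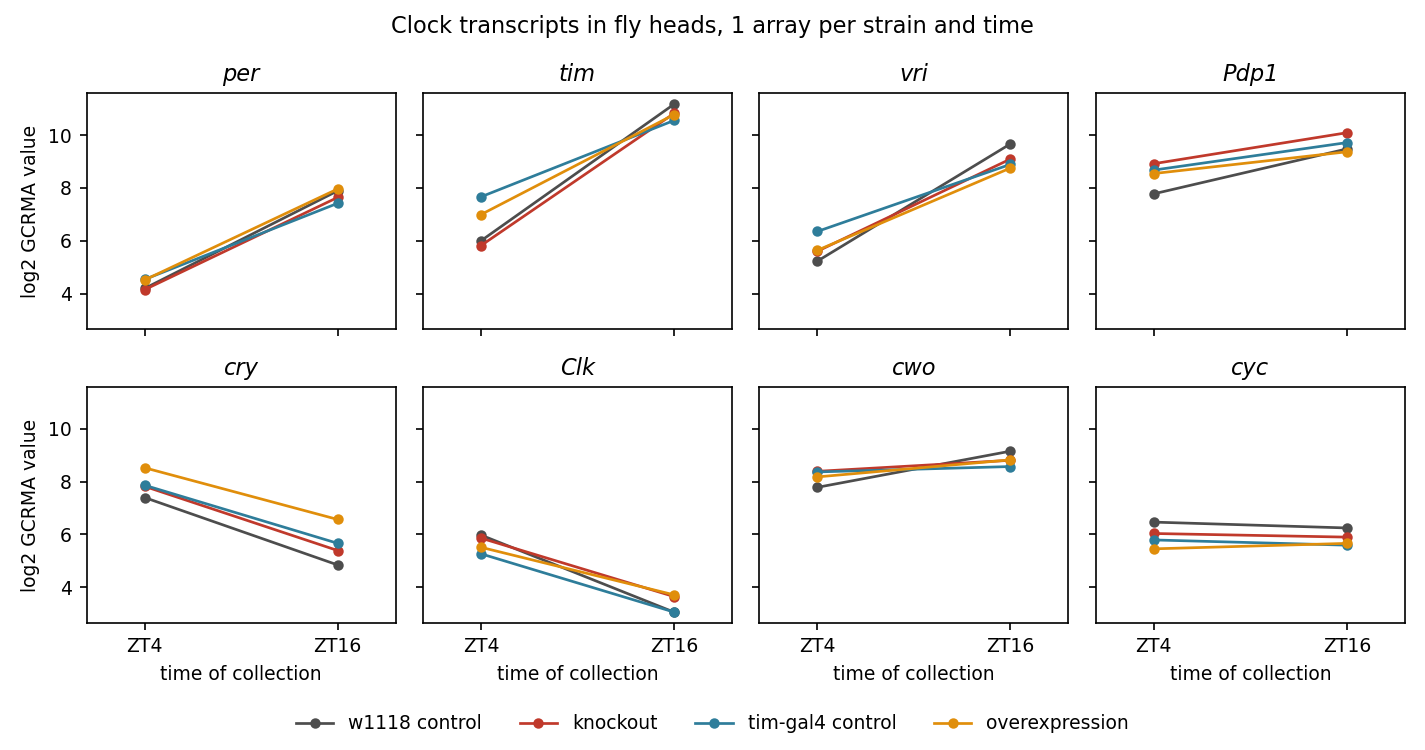
Log2 GCRMA values of clock genes at ZT4 and ZT16, with 1 point per array and a line for each of the 4 strains. The lines of per, tim and vri climb and those of Clk and cry descend in all 4 strains.

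Outside these lists, the other large rises were in gol, a membrane-bound ubiquitin ligase (1.63), CG31100 (1.07), the guanine nucleotide exchange factor gene Exn (0.93), Gfat1, which starts hexosamine synthesis (0.90), js (0.82), CG5966 (0.82) and CG2681 (0.78). The other large falls on the log2 scale were in GstZ2, a glutathione transferase (-1.68), CG15211 (-1.19), peg (-1.04), hgo, an enzyme of tyrosine breakdown (-0.94), Swim (-0.93), Swip-1 (-0.90) and Pcyt2, an enzyme of phosphatidylethanolamine synthesis (-0.87). Of the 41 detoxification enzymes, the cytochrome P450 gene Cyp6d5 rose by 0.82 (SE 0.07), while the juvenile hormone esterase gene Jhe fell by 1.56 and Ugt302C1 fell by 0.97 on the log2 scale. The values of Jhe were low (4.07 at ZT4 and 2.51 at ZT16). A further 38 of these enzymes were not called, and 15 passed when adjusted over the list alone.

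The photoreceptor, chemoreception, stress, fat body and hemocyte lists had no called member over all genes, while 3 of 15, 1 of 16, 1 of 8, 3 of 7 and 1 of 10 passed when adjusted over the list alone. Differences among their members included -0.94 for the protein kinase gene inaC (adjusted p = 0.0701 in limma), -0.76 for its scaffold inaD (0.0602), 2.98 for the odorant-binding protein gene Obp99a (0.0701), 0.89 for Hsp27 (0.102), -0.81 for the lipase-like gene sxe2 (0.0602) and 0.63 for lz (0.0963). In the lists of feeding hormones (12 genes), carbohydrate metabolism (19), lipid metabolism (22), immune genes (15), ribosomal proteins (33), neurons (15) and glia (10), limma called none, and none passed when adjusted over the list alone. The muscle, gut, testis and accessory gland lists were shifted up as wholes in camera, with medians of 0.34, 3.56, 2.18 and 3.29 on the log2 scale and adjusted p-values of 5.8e-06, 2.7e-05, 1.1e-07 and 1.1e-07, each an adjusted p of 0.579 with an estimated correlation. None of their members was called. Within the strains the accessory gland and gut medians changed by 0 in the w1118 control and under overexpression and by 6.17 to 7.15 in the other 2.

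In all, 31 of 8300 probe sets were called, 13 higher and 18 lower at ZT16, and 14 of them differed at least 2-fold. An unadjusted p under 0.05 was found for 1371 probe sets, against 415 by chance. Most of the calls had an adjusted p of 0.0499 in limma, just under the threshold. The count was 0 or 1 without any 1 of the 8 arrays and 0 without the knockout ZT16 and tim-gal4 control ZT16 arrays, 0 with no filter, 3 (2 higher, 1 lower) after quantile normalization, 9 with 1 value per gene, 7 without the strain block and 234 with trended and robust moderation. Without the 372 probe sets high in those 2 arrays it was 292, of which 81 were higher and 211 lower.

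The second comparison asked which transcripts differ when part of the cluster is deleted. The largest fall in the knockout was in Elovl7, a member of the fatty acid elongase family, whose log2 value was 8.95 in w1118 and 2.54 in the knockout (difference -6.41, SE 0.11, adjusted p = 0.000112 in limma). Ect3 followed with 7.58 against 2.56 (-5.02, SE 0.22). Syt7, which encodes a synaptotagmin of vesicle release, fell by 4.24 (SE 0.26), and repo, the transcription factor of glial identity, fell by 2.54 (SE 0.30, from 8.65 to 6.11) on the log2 scale. The highest rises were in CG9377 (4.16, SE 0.25), the metallothionein gene MtnD (3.76, SE 0.27), CG3397 (3.75, SE 0.20), CG4962 (3.45, SE 0.10) and the zinc transporter gene Zip102B (3.40, SE 0.14). These were called in limma with adjusted p-values of at most 0.0272. All called probe sets had the same direction at ZT4 and ZT16. The model takes strain differences in time change as its error and so favours such probe sets, which makes this no separate evidence.

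Further rises were found for CG13022 (3.08), the activin-family ligand gene Actbeta (2.79), CG18549 (2.66), CG7900 (2.65), hoka (2.64), CG8012 (2.63) and CG1774 (2.44). Further falls on the log2 scale were found for Tektin-C, a microtubule protein of cilia (-4.13), CG8745 (-3.80), the drosomycin-like peptide gene Drsl4 (-3.34, from 11.30 to 7.96), the cytochrome P450 genes Cyp4ac2 (-3.30) and Cyp4e3 (-2.67), the glycosyltransferase gene Ugt35C1 (-2.80), CG5953 (-2.50) and the cuticle protein gene Cpr11B (-2.42). Of the 131 probe sets called, the knockout lay within 2-fold of the tim-gal4 control in 71, at least 2-fold beyond it in the direction of the call in 52, and at least 2-fold from it in the other direction in 8. For CG9377 the levels were 8.38 in the knockout, 8.48 in the tim-gal4 control and 4.22 in w1118, and for Tektin-C 2.60, 2.67 and 6.74. In Elovl7 the tim-gal4 control read 8.63, near w1118, and in MtnD the levels were 6.79, 2.68 and 3.04. The w1118 levels of CG3397 and hoka were 2.35 and 2.34, near the lowest value, so that the sizes of their rises are not quantitative.

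**Figure D3:**
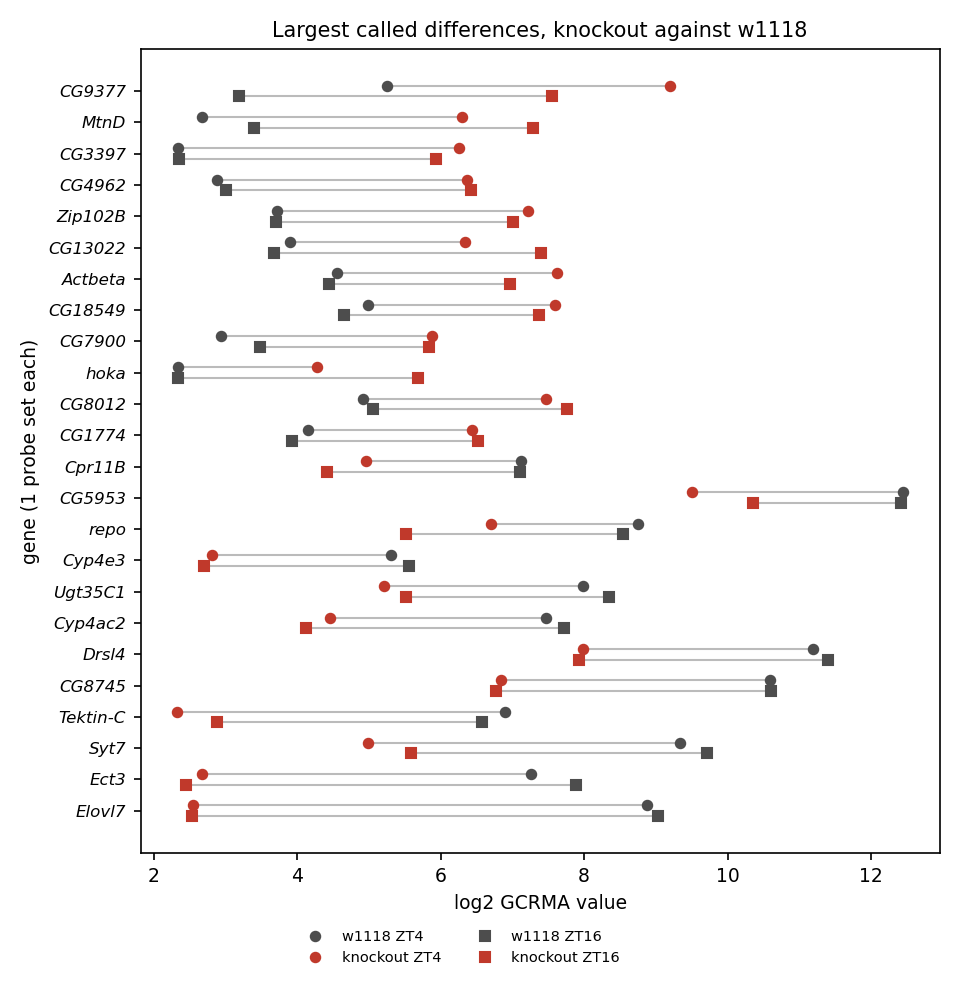
Log2 GCRMA values of the largest called rises and falls in the knockout, with circles for ZT4, squares for ZT16 and 1 point per array. Both pairs of arrays show each difference, as the choice of genes required. Elovl7, Ect3 and Tektin-C lie near the lowest value of 2.32 in the knockout, and CG3397 and hoka lie near it in w1118.

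Among the fixed lists, 1 of 10 glial genes (repo) fell, 1 of 10 hemocyte genes rose and 1 of 22 lipid metabolism genes rose. The genes that rose were PPO2, the prophenoloxidase of crystal cells (1.21, SE 0.16, adjusted p = 0.0392 in limma), and Men, which encodes malic enzyme (1.05, SE 0.14, adjusted p = 0.0408 in limma). Levels of PPO2 were 6.67 in w1118, 7.88 in the knockout and 9.16 in the tim-gal4 control, and those of Men 9.85, 10.90 and 10.65. Of 41 detoxification enzymes, 2 fell (Cyp4e3 and Ugt35C1) and 39 were not called. Adjusted over the list alone, 4 hemocyte, 2 lipid, 2 detoxification and 1 glial gene passed, as did 2 of 12 feeding hormone genes, 2 of 16 chemoreception genes, 1 of 19 carbohydrate genes and 1 of 7 fat body genes, which had no call over all genes. The insulin receptor gene InR differed by -0.64 (adjusted p = 0.143 in limma), the odorant-binding protein gene Obp19b by -1.22 (0.125), the storage protein gene Lsp2 by 1.72 (0.116) and the glucosidase gene tobi by 5.76 (0.0775), where tobi is among the probe sets high in the 2 arrays with body-tissue markers. No member of the core clock (13), cycling (13), immune (15), stress (8), photoreceptor (15), ribosomal (33), neuron (15) or muscle (12) lists was called by limma, and none passed when adjusted over the list alone. The differences of Fbxl4, Pdp1, cry and Pdf were 0.96, 0.88, 0.48 and -0.47, and that of tim was -0.26. The gluconeogenesis gene Pepck1 is not among the 19 carbohydrate genes counted here. It was called higher in the knockout (adjusted p = 0.0161 in limma). Its levels were 10.49 in w1118, 12.46 in the knockout and 12.89 in the tim-gal4 control.

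As wholes, 10 lists were shifted in camera, and none of these calls held with an estimated correlation (adjusted p = 0.589 for each). Hemocyte genes were shifted up (median 0.28, adjusted p = 0.000103), as were lipid metabolism (0.10, 0.0053) and carbohydrate metabolism (0.12, 0.0095), and detoxification enzymes (median 0.12, adjusted p = 0.0264), whose mean was -0.05 and whose called members fell. Photoreceptor genes (median -0.26, adjusted p = 0.0264) and glial genes (median -0.24, adjusted p = 0.0171) were shifted down, with negative differences in all 15 and all 10 members, of which 0 and 1 were called. Without the 2 arrays with body-tissue markers only the hemocyte and lipid calls stood, with medians of 0.37 and 0.11. Muscle (0.15), gut (3.57), testis (2.09) and accessory gland (3.54) were shifted up with adjusted p-values of 0.0264, 0.00042, 2.1e-05 and 1.4e-05, and the muscle median was -0.22 without these arrays.

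In all, 131 of 8300 probe sets were called in the knockout, 63 higher and 68 lower, standing for 101 genes, and 109 of them differed at least 2-fold. An unadjusted p under 0.05 was found for 1170. The count was 2 without either w1118 array, 17 and 24 without the knockout ZT4 and ZT16 arrays, 61 without either tim-gal4 control array and 64 without either overexpression array. It was 0 without the 2 arrays with body-tissue markers and 170 with a term for them, 0 with the 4 arrays of this comparison alone, 30 with no filter, 75 with 1 value per gene and 246 with trended and robust moderation. Without the 372 probe sets high in those arrays it was 296.

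The third comparison asked which transcripts differ when tim-gal4 drives the cluster. In the flies with the transgene, Ance-4, a relative of angiotensin-converting enzyme, was at background (2.54) against 9.35 in the tim-gal4 control (difference -6.81, SE 0.12, adjusted p = 0.000117 in limma). Pdf, the neuropeptide of clock neurons, fell by 1.77 (SE 0.16), while cry rose by 0.78 (SE 0.17). Among the hormone genes of feeding and growth, ImpL2, whose product binds insulin-like peptides, rose by 2.06 (SE 0.18), the insulin-like peptide genes Ilp5 and Ilp2 rose by 0.77 (SE 0.17) and 0.69 (SE 0.15), and the adipokinetic hormone receptor gene AkhR fell by 0.85 (SE 0.15) on the log2 scale. Adjusted p-values in limma for these hormone and clock genes lay between 0.0050 and 0.0341.

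The largest rises were in CG11458 (4.55, SE 0.23), CG33158 (3.69, SE 0.14), CG11854 (3.68), Diedel, a secreted immune regulator (3.41, SE 0.80), CG14419 (3.16), path, an amino acid transporter (2.92), Usp10 (2.69), CG16985 (2.62), CG6912 (2.54), GstE7 (2.52), Nepl4 (2.5) and CG3588 (2.47). After Ance-4 the largest falls on the log2 scale were in CG4306 (-5.28, SE 0.12), tobi (-5.18, SE 0.97), Osi6 (-5.12, SE 0.28), Cyp6a17 (-4.98, SE 0.22), CG30083 (-4.83), CG30002 (-4.22), Cyp6t1 (-4.16), lncRNA:CR33942 (-3.99), the growth factor gene Idgf5 (-3.83), the Toll-pathway peptide gene BomBc3 (-3.80) and CG11842 (-3.72). Of these, tobi is among the probe sets high in the 2 arrays with body-tissue markers. In CG11458, CG14419, path, Osi6 and tobi, w1118 differs from the tim-gal4 control in the same direction as overexpression does. Levels of path were 9.98 in w1118, 6.10 in the tim-gal4 control and 9.02 under overexpression. Such differences cannot be credited to the transgene. For Cyp6t1 the levels were 6.8, 6.6 and 2.5, with w1118 near the tim-gal4 control. The calls as a whole were not set against w1118.

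**Figure D4:**
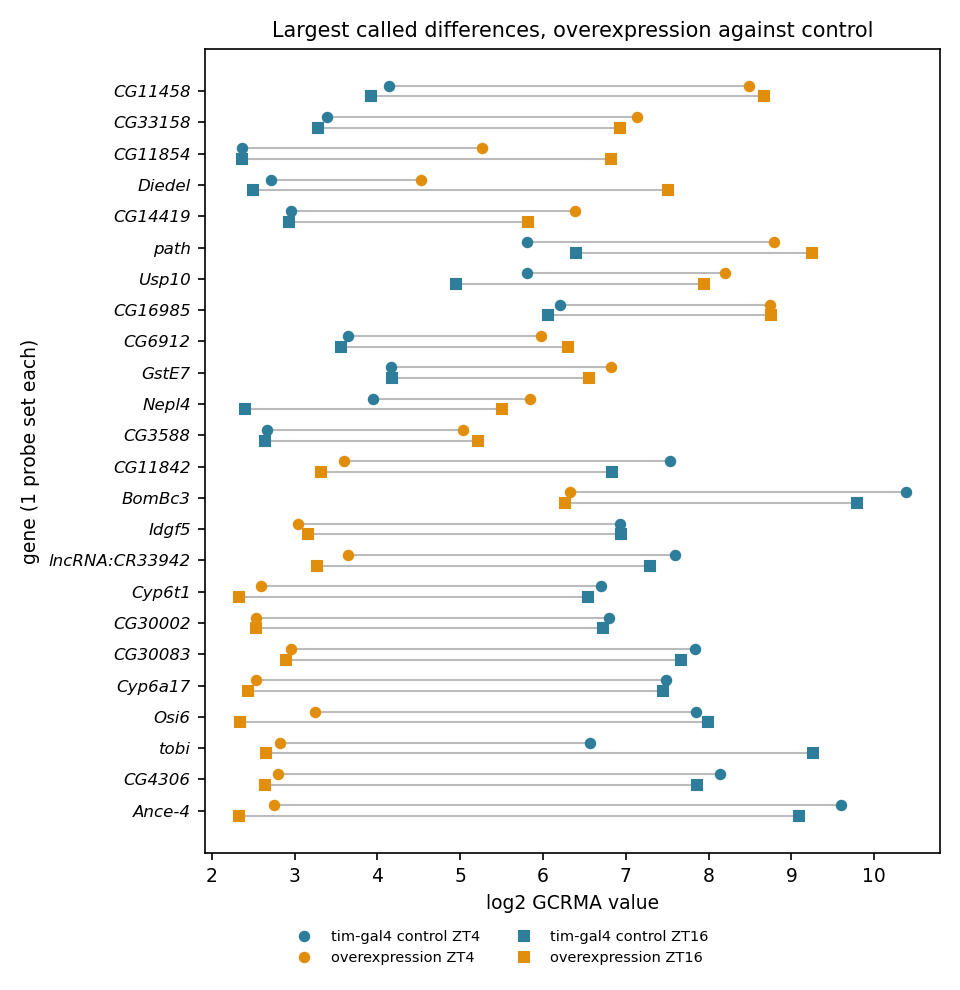
Log2 GCRMA values of the largest called rises and falls under overexpression, with circles for ZT4, squares for ZT16 and 1 point per array. Both pairs of arrays show each difference, as the choice of genes required. Ance-4 and Cyp6t1 lie near the lowest value of 2.32 under overexpression.

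Of the 41 detoxification enzymes, 6 rose, 14 fell and 21 were not called, and 23 passed when adjusted over the list alone. The falls on the log2 scale included Cyp6a17, Cyp6a2 (-3.64, SE 0.12), Cyp6a20 (-3.62, SE 0.16) and Cyp4e3 (-2.83, SE 0.34). The list as a whole was shifted down in camera (median -0.22, adjusted p = 0.0090), with an adjusted p of 0.989 with an estimated correlation.

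In the core clock list 4 genes rose, 1 fell and 8 were not called, and 5 passed when adjusted over the list alone. The F-box gene Fbxl4 rose by 1.57 (SE 0.26) and the F-box gene slmb by 0.45 (SE 0.10), while tim differed by -0.23 (SE 0.58, not called) with a second probe set of opposite sign. Of the 13 cycling transcripts, e rose by 0.58 and CG42329 fell by 1.5 on the log2 scale, and 1 passed when adjusted over the list alone. Of 12 feeding and metabolic hormone genes, 3 rose, 1 fell and 8 were not called, and 7 passed when adjusted over the list alone.

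Of 19 carbohydrate genes, 5 rose, 3 fell and 11 were not called. Among those called were the maltase genes Mal-B1 (1.12, SE 0.26) and Mal-B2 (-1.32, SE 0.22) and the hexokinase gene Hex-C (-1.40, SE 0.29), and 10 of the list passed when adjusted over the list alone. Of 22 lipid genes, 3 rose, 3 fell and 16 were not called, with values of 0.65 for the regulator SREBP, -0.83 for the fatty acid synthase gene FASN1, -0.90 for the lipophorin receptor gene LpR2 and -0.71 for Lsd-2, which coats lipid droplets. In that list 10 passed when adjusted over the list alone. Lsp2 was the 1 of 7 fat body genes called (-3.24, SE 0.34), and 1 passed when adjusted over the list alone. Pepck1, which is not among the 19 carbohydrate genes counted, was called lower (adjusted p = 0.00484 in limma). Its differences were -2.41 at ZT4 and -2.06 at ZT16.

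Among 15 immune genes, Tep4 (0.57) and the Toll ligand gene spz (0.45) rose while BomS2 fell by 1.39 and pirk, a brake of the Imd pathway, fell by 0.75 on the log2 scale, and 4 passed when adjusted over the list alone. The small heat shock protein gene Hsp27 was the 1 of 8 stress genes called (1.40, SE 0.22), and 1 passed when adjusted over the list alone. Of 16 chemoreception genes, Obp99b rose (1.81, SE 0.35), Obp99a (-3.63, SE 0.58) and Obp57c (-0.82, SE 0.12) fell, and 4 passed when adjusted over the list alone. The called members of the head tissue and hemocyte lists were ninaB, which makes retinal (1.06), among 15 photoreceptor genes, VGlut (0.78) among 15 neuronal genes, loco (0.86) and the GABA transporter gene Gat (0.75) among 10 glial genes, and Pxn (0.54), Col4a1 (0.61) and srp (-0.56) among 10 hemocyte genes. Adjusted over the list alone, 1, 1, 3 and 4 passed. In the muscle list up rose by 0.76 and Mlp60A fell by 0.60, with 2 of 12 passing when adjusted over the list alone. RpL27 was the 1 of 33 ribosomal protein genes called (-0.50), and 0 passed in limma when adjusted over the list alone. Gut, testis and accessory gland genes were shifted down as wholes in camera, by medians of -3.29, -2.13 and -3.08 on the log2 scale with adjusted p-values of 0.0410, 0.0090 and 0.0101 (each an adjusted p of 0.989 with an estimated correlation), with no called member. On the tim-gal4 control ZT16 array these lists had median levels of 8.97, 6.59 and 8.49.

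In all, 1698 of 8300 probe sets (20.5%) were called under overexpression, 1185 higher and 513 lower, standing for 1457 genes, and 526 differed at least 2-fold. An unadjusted p under 0.05 was found for 3000. After median centring of each array the split was 948 higher and 621 lower. With the 4 arrays of this comparison alone it was 4 higher and 10 lower. Calls were more often lower than higher without the ZT16 array of either strain, and more often higher without the ZT4 array of either. The excess of higher calls thus depends on the setting. The count was 313 and 219 without the tim-gal4 control ZT4 and ZT16 arrays, 266 and 131 without those of overexpression, 856 without either knockout array, 0 without the 2 arrays with body-tissue markers, 1644 with a term for them, 14 with the 4 arrays of this comparison alone and 648 with no filter.

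The 2 control strains, which differ in background and in the driver, served as a measure of how far strains differ without a change in the cluster. Their comparison does not separate strain from sample preparation, since control probe sets for 18S ribosomal RNA and for added bacterial transcripts had median differences of 2.99 and 0.96 between the 4 arrays of the w1118 control and the knockout and the 4 of the tim-gal4 strains. The w1118 control had more RNA than the tim-gal4 control of CG14419 (6.34, SE 0.29), CG11458 (5.99, SE 0.23), CG3348 (4.67, SE 0.58), Tektin-C (4.06, SE 0.25) and path (3.88, SE 0.18). It had less of CG16713 (-6.24, SE 0.24), Osi6 (-5.59, SE 0.28), tobi (-5.37, SE 0.97), Cyp12d1-d (-4.29, SE 0.30) and CG9377 (-4.26, SE 0.25). Of 22 lipid metabolism genes 8 were lower and 1 was higher, with 13 passing when adjusted over the list alone, and the list was shifted down as a whole in camera (median -0.47, adjusted p = 9.9e-05). Carbohydrate metabolism (median -0.49, adjusted p = 0.0108) and detoxification enzymes (-0.22, 0.0397) were shifted down too, as were the gut, testis and accessory gland lists, and none of these 6 calls held with an estimated correlation (adjusted p = 0.934). Of 15 neuronal genes 7 were higher and 2 lower, with 11 passing when adjusted over the list alone. Of 16 chemoreception genes 7 were higher and 3 lower, and of 10 glial genes 4 were higher.

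In all, 2567 probe sets (30.9%) differed between the control strains in limma, 1655 higher and 912 lower in w1118. After median centring, which moved the median difference of all probe sets from 0.11 to 0.01 on the log2 scale, 1258 were higher and 1166 lower. The count was 1253 and 754 without the w1118 control ZT4 and ZT16 arrays, 1239 and 819 without those of the tim-gal4 control, 1699 without either knockout array, 1100 with no filter, 0 without the 2 arrays with body-tissue markers and 2323 with a term for them.

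Whether the change from ZT4 to ZT16 itself differs in the manipulated strains was tested last. No clock gene was found to change differently, although the errors were wide. Against the other 3 strains, the time change in the knockout differed by 0.15 (SE 0.38) for per, 1.05 (SE 0.92) for tim, 0.13 (SE 0.79) for vri, 0.10 (SE 0.48) for Clk and -0.19 (SE 0.30) for cry. Under overexpression the differences were 0.09 (SE 0.38) for per, -0.57 (SE 1.03) for tim, -0.38 (SE 0.78) for vri, 0.65 (SE 0.37) for Clk and 0.44 (SE 0.23) for cry. Against the strain's own control alone, where single arrays allow no test, several of these differences have the other sign. In the order per, tim, vri, Clk and cry they are -0.20, -0.17, -0.94, 0.71 and 0.12 for the knockout and 0.56, 0.89, 0.58, 0.41 and 0.24 for overexpression. None of the 13 core clock genes was called in limma in either fit, and none passed when adjusted over the list alone. No probe set was called in limma at all, with 169 (knockout) and 216 (overexpression) at an unadjusted p under 0.05 against 415 by chance.

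As wholes, the change from ZT4 to ZT16 of the stress genes was shifted up in the knockout against the other strains in camera (median difference 0.57, adjusted p = 0.000272), and that of the glial genes down (-0.19, adjusted p = 0.0075), each with an adjusted p of 0.687 with an estimated correlation. The knockout ZT16 array is 1 of the 2 with body-tissue markers, and with a term for these only the stress call stood, with medians of 0.72 for stress and -0.25 for glia. Without either tim-gal4 control array neither list was called. The muscle, gut, testis and accessory gland lists were shifted up for the knockout (medians of 4.51, 2.67 and 4.92 for the last 3) and down for overexpression, with an adjusted p of 0.687 and 0.932 with an estimated correlation. With no filter 255 (knockout) and 68 (overexpression) probe sets were called. Without either tim-gal4 control array 357 were called for the knockout, all higher, and without either w1118 array 381 for overexpression, 11 higher and 370 lower. In each, 353 of them were among the 372 probe sets high in the 2 arrays with body-tissue markers.

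The knockout and overexpression comparisons share no array and were set side by side. Each does hold 1 of the 2 arrays with body-tissue markers, the knockout ZT16 and the tim-gal4 control ZT16 array. Transcripts high on both are therefore higher in the knockout and lower under overexpression at ZT16 by construction. At both times, 14 probe sets were at least 2-fold higher in the knockout and at least 2-fold lower under overexpression, where unrelated lists would share 1.63. A further 5 were lower in the knockout and higher under overexpression, where 1.57 would be shared. In the same direction, 2 were higher and 6 lower in both, where 1.76 and 1.45 would be shared. Among the opposite ones were Pepck1, a key enzyme of gluconeogenesis, with knockout differences of 1.99 at ZT4 and 1.94 at ZT16 and overexpression differences of -2.41 and -2.06, and Lsp2, with 2.01 and 1.43 against -3.89 and -2.59. CG4962 had 3.48 and 3.41 against -1.41 and -1.36. With the other sign, Ect3 had -4.59 and -5.45 against 1.28 and 1.52, and path -1.07 and -1.5 against 2.98 and 2.85. The others with 1 symbol were tobi, Cyp4d20, CG8654, CG3513, CG1774, Obp8a, CG11741, CG13022 and CG3857. In 12 of the 14 the tim-gal4 control lay above w1118 in the mean of both times, and in 4 of the 5 below it, as for Pepck1 with ZT4 levels of 10.49 in w1118, 12.48 in the knockout, 12.76 in the tim-gal4 control and 10.34 under overexpression. These genes were singled out by this count after their values were seen.

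Across all probe sets, which are not independent of one another, the Spearman correlation of the 2 comparisons was -0.11 over both times, -0.01 at ZT4 and -0.17 at ZT16. It was 0.015 without the 372 probe sets high in the 2 arrays with body-tissue markers.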

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

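The test of this part was chosen only after the values of the control probe sets had been seen. Among the probe sets left out of the comparisons, 1 control probe set was picked for the widest gap between 2 groups of arrays. It was above background on the 4 arrays of the strains that carry tim-gal4. On the 4 arrays of the w1118 control and the knockout it was near background. Its mean was 4.69 against 2.43, a difference of 2.26 on the log2 scale, and its highest value in the w1118 control and the knockout was 2.68. From ZT4 to ZT16 it went from 3.47 to 5.89 in the tim-gal4 control. Under overexpression it went from 3.60 to 5.80, so that at ZT4 it lay under the filter level of 4 in both strains. It drew attention as a signal in data outside the comparisons, above the level in strains without the driver. The annotation used here does not name its target, and no explanation was tested.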

How the results depend on the processing

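The fits without the 2 arrays with body-tissue markers (knockout ZT16 and tim-gal4 control ZT16), with a term for them, and without the 372 probe sets high in them were chosen only after the data had been seen. Replicate numbers pair no samples, since each group has 1 array, while the strain block pairs the ZT4 and ZT16 arrays of each strain. A fit without 1 array leaves a strain with a single array, which is assumed to vary like the others, and has 2 residual degrees of freedom in place of 3. Without the 2 arrays 1 is left. Where a count dropped in these fits, fewer arrays are part of the change. For all other changes given here the cause was not tested.

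For ZT16 against ZT4, 31 probe sets were called. The count was 0 with no filter, 64 with a filter at log2 6, 60 with values under 4 set to 4, 3 after quantile normalization, 234 with trended and robust moderation, 9 with 1 value per gene and 14 with a 2-fold threshold. It ranged from 0 to 1 without each array in turn. In this comparison, leaving out either array of a strain gives the same fit as leaving out the strain, so these are not separate checks. The count was 0 without the w1118 control, 0 without the knockout, 1 without the tim-gal4 control, 0 without overexpression and 0 with the 2 control strains alone. It was 7 without the strain block, 3 with a time effect per background, 0 without the 2 arrays, 4 with a term for them and 292 without the 372 probe sets. Among the settings with 0 calls, limma gave between 327 and 1748 probe sets with an unadjusted p under 0.05.

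For the knockout, 131 probe sets were called. The count was 30 with no filter, 246 with trended and robust moderation, 75 with 1 value per gene, 2 to 64 without each array in turn, 0 with the 4 arrays of the comparison alone (716 in limma with an unadjusted p under 0.05), 0 without the 2 arrays (728), 170 with a term for them (106 higher, 64 lower) and 296 without the 372 probe sets. Under overexpression 1698 were called. The count was 648 with no filter, 526 with a 2-fold threshold, 131 to 1252 without each array in turn, 14 with the 4 arrays of the comparison alone, 385 by a rule of 2-fold the same way at both times, 1644 with a term for the 2 arrays and 0 without them (2355 in limma with an unadjusted p under 0.05). Between the control strains 2567 were called. The count was 1100 with no filter, 839 with a 2-fold threshold, 754 to 1902 without each array in turn, 595 by the 2-fold rule, 2323 with a term for the 2 arrays and 0 without them (2801 in limma with an unadjusted p under 0.05). The time change in the knockout, with 0 calls, had 255 with no filter, 1 with values under 4 set to 4 and 0 to 357 (all higher) without each of the 6 arrays of the other strains in turn. That under overexpression, with 0 calls, had 68 with no filter and 0 to 381 (11 higher, 370 lower) without each of the 6 arrays of the other strains in turn. Of the 357 and of the 381, 353 were among the 372 probe sets. Without an array of the manipulated strain itself, no time change can be fitted for it.

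Of the lists, camera called 4 for the time of day, 10 for the knockout, 4 for overexpression, 6 between the controls, 6 for the time change in the knockout and 4 for that under overexpression. With an estimated correlation the count was 0 in each of these 6 comparisons. Without each array in turn the counts ranged from 4 to 10, 2 to 11, 1 to 4, 1 to 6, 5 to 7 and 3 to 6, the last 2 over the 6 arrays of the other strains. Quantile normalization gave 7 for the time of day, and no filter gave 2 for the time change under overexpression. Without the 2 arrays the counts were 0, 2, 0 and 2 for the first 4 comparisons. With a term for them the counts of the 6 comparisons were 1, 3, 0, 1, 3 and 1, and without the 372 probe sets 2, 6, 1, 2, 3 and 1.

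Some list medians changed sign or went to 0. The accessory gland median for the time of day went from 3.29 to 0 without the 2 arrays. The muscle median for the knockout went from 0.15 to a range of -0.20 to 0.42 without each array in turn (lowest without the w1118 control ZT16 array), -0.22 without the 2 arrays and -0.24 with a term for them. With that term the accessory gland medians for overexpression and between the controls went from -3.08 to 0.17 in both, the gut median for the time change in the knockout from 4.51 to -0.083, and for the time change under overexpression the muscle median from -0.40 to 0.10, the gut median from -4.75 to 0 and the accessory gland median from -4.38 to 0. The 19 probe sets that differed in opposite directions in the knockout and overexpression comparisons became 54 at 1.5-fold, 35 at ZT4 alone, 444 at ZT16 alone and 72 there without the 372 probe sets. The 8 that differed in the same direction became 41, 20, 28 and 28. The Spearman correlation of -0.11 became -0.24 with no filter and 0.015 without the 372 probe sets.

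No called named gene changed direction under any setting run. For the named genes called for the time of day, 148 combinations of gene and setting kept the call and 472 lost it. The numbers were 357 and 187 for the knockout, 881 and 433 for overexpression and 184 and 15 between the controls. Settings that give the same fit were each counted, as without either array of a strain for the time of day. These numbers therefore hold repeats. Transcripts near the lowest value of 2.32 cannot show a fall, which limits what low signal over background allows.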

Other observations

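The tests of body tissue, time of day and normalization for the 2 arrays with body-tissue markers were chosen only after the data had been seen, as was the count of splits without the 372 probe sets high in these arrays.

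Genes called in the knockout lay on all 5 large chromosome arms. They made up 1.97% of 1319 measured genes on 3L (26 genes) and 2.01% of 1693 on 3R (34 genes), against 0.212% of 1416 on 2R (3 genes), 1.10% of 1270 on 2L (14 genes) and 1.10% of 1089 on X (12 genes). Whether these shares differ was not tested.

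Probe sets for 18S ribosomal RNA, which belong to the array controls, were higher on all 4 arrays of the w1118 control and the knockout than on the 4 arrays of the tim-gal4 strains, in 3 of 3 cases. The median difference was 2.99 on the log2 scale. Of 19 measured probe sets for bacterial transcripts added during labelling, 16 were higher on these 4 arrays, with a median difference of 0.96. None of the 11 probe sets for hybridization controls was, with a median difference of -0.23. Among 27 other control probe sets that passed the filter, 0 were higher on these 4 arrays and 10 were higher on the 4 arrays of the tim-gal4 strains. Their median difference was -0.37. The strain background and the preparation of the samples cannot be told apart in the comparison of the control strains.

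High accessory gland and gut transcripts on the knockout ZT16 and tim-gal4 control ZT16 arrays may come from body tissue carried over with the heads, a hypothesis found and tested on the same data. The smaller of the median rises of both lists in both strains was 6.17 on the log2 scale, far above the changes of the neuron, glia and photoreceptor lists. The filter keeps a gene at background elsewhere only if both arrays are high, which partly fixed this rise in advance. With no filter, the median of 14 accessory gland genes went from 2.33 to 9.35 in the knockout and from 2.32 to 8.23 in the tim-gal4 control. That of 26 gut enzymes went from 2.32 to 3.83 and from 2.32 to 3.46, short of the rise over 3 set for this test. Time of day would raise the accessory gland list in every strain, but the larger of its median changes in the w1118 control and under overexpression was 0. For a shift by the normalization, the larger of the median shifts of all probe sets in the knockout and the tim-gal4 control was -0.173 on the log2 scale. GCRMA normalizes the arrays together, which holds such a shift small in advance, so this value leaves the normalization open. How such tissue came into these samples was not tested.

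The breadth of the difference under overexpression could reflect strain background or the dose of the miRNA cluster, and neither was decided. Among the 500 leading genes, 17.2% had an adjacent measured gene among them, which is -2.4 percentage points relative to the 19.6% of the time comparison, where random lists had a median of 14% and an upper bound of 18.2%, which the time comparison itself exceeds. The 2 control strains, which do differ in background, reached 18.2%, also below the time comparison, so that this measure misses a background difference and leaves it open. For dose, a Spearman correlation of knockout and overexpression differences at ZT4 below -0.1 was predicted. It was -0.011 (95% bootstrap interval -0.033 to 0.012), so the prediction was not met. The interval resamples probe sets, which are not independent, and holds no error between arrays, since each strain and time has no replicate. Over the 1698 called probe sets, which were called from the same overexpression arrays, the value was -0.050 (interval -0.101 to 0.005). The prediction also assumed that a transgene acts on the transcripts that the natural level of the cluster changes, which was not tested. The correlation therefore does not decide on dose, which stays open as well. Insertion site of the transgene and rearing of the strains, other differences that the design holds, were not tested.

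Calls in the knockout could sit around the targeted locus if flanking sequence differed between the strains. Of 50 measured genes on each side of the cluster 1 was called (1%, 95% Clopper-Pearson interval 0.0253% to 5.45%), the gene Cyp4ac2, against 92 of 6744 elsewhere (1.36%). The one-sided Fisher's exact test gave p = 0.748, and an interval this wide leaves flanking sequence open. Loss of the miRNAs themselves and background away from the locus were not tested. Of the 500 leading genes of the knockout comparison, 20.2% had an adjacent measured gene among them, where random lists had an upper bound of 18.2%. The time comparison, made within strains, exceeds that bound too with 19.6%, so this measure leaves background open.

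Chance cannot be excluded for the 31 probe sets called between ZT16 and ZT4 on this count alone. All 31, the 5 core clock genes among them, moved the same way in all 4 strains. The model takes strain differences in time change as its error and so favours such probe sets, which makes this no separate evidence. Of 35 splits of the 8 arrays into 4 and 4, the strain block left no fit for 3. Of the other 32, 3 called as many, the real one included. Splits that part only 2 strains come in pairs with the same fit, so the 32 are not all distinct. The highest count of the others was 763, in 2 splits that give the same fit. That fit sets the knockout ZT16 and tim-gal4 control ZT16 arrays against the ZT4 arrays of the same strains, which points to a structure of the samples. Of the 8 splits that part both arrays of all 4 strains, the real one called 31 and the highest other 0, and 8 splits are too few for a share under 0.05. Without the 372 probe sets the real split called 292 and the highest of the others 28. Thus 1 of 32 splits, repeats of the same fit included, called as many. This count was chosen only after the data had been seen. The 372 were picked by the same 2 arrays that set apart the splits with 763 calls, so leaving them out lowers those splits by construction. Only the 8 splits that part all 4 strains are built like the real one, so this count does not decide on chance either.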
